A study of Mus musculus with 6 samples.

How the data were processed

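Single-cell RNA sequencing was used on dissociated SM1 mouse melanoma flank tumours taken at the endpoint, with 1 library for each of 6 treatments. The treatments were control IgG, anti-PD1, anti-LAG3, anti-CTLA4, anti-PD1 with anti-LAG3 (the PD1/LAG3 combination) and anti-PD1 with anti-CTLA4 (the PD1/CTLA4 combination). The deposited values are UMI counts per gene and cell barcode, which the authors made from 10x Chromium libraries run on a NextSeq 500. The submitters' processing notes name Cell Ranger 6.0.0 and the mm10 genome. The chemistry version, the gene annotation and the read filters are not given in the sources used here. Gene coordinates below come from the GENCODE annotation of GRCm38, which is the same assembly as mm10.

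The 6 count tables held 9412 barcodes, 32285 genes and 110299680 UMIs. In the order IgG, anti-PD1, anti-LAG3, anti-CTLA4, PD1/LAG3 and PD1/CTLA4, the libraries held 1556, 1676, 1579, 1746, 2016 and 839 barcodes. A cell was kept with at least 200 genes and at most 20% mitochondrial UMIs, which removed 545 barcodes. Scrublet, as built into scanpy 1.11.5 and run on each library alone with 30 components, removed 111 more cells as doublets (1.25%). The 8756 cells kept numbered 1372, 1550, 1476, 1620, 1945 and 793. Their median depth was 22201, 5877, 16578, 4795, 2146 and 9124 UMIs, a 10.3-fold range. Their median mitochondrial share was 1.99%, 2.03%, 2.05%, 2.43%, 3.55% and 2.17%.

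Counts of all kept cells were scaled to 10000 UMIs per cell and log transformed, and 2000 variable genes were reduced to 30 principal components. A shared-neighbour graph of 15 neighbours was divided by leidenalg 0.10.2 at resolution 1.0 with seed 0, which gave 23 clusters. A class marker counted as present with a UMI in at least 10% of a cluster's cells and a level at least 2-fold over the median of the clusters. A cluster took the class with the largest share of its markers present, if at least 3 were. It was left unnamed if its leading 10 genes held more markers of another class, or if its cells were shallow and its leading genes held no marker of its own class. The leading 10 genes were ranked by fold over the median of the clusters with 0.1 UMIs per 10000 added, a definition set after the data were seen, in place of fold over all other cells, which left cluster 6 without a name. Names such as T cell-like refer to these marker lists, which covered 18 classes. T and NK cells (2220 cells) were clustered again into 9 subclusters, and a subset name needed 2 of its own leading markers, also set after the data were seen. Only cycling and NK subsets were named this way. A cluster with no class name held at most 1.39% of a library, in PD1/LAG3.

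UMIs were summed over the cells of a class in a library and scaled to the UMIs of that class as counts per 1e6, written CPM, with exact Poisson intervals for sums, exact binomial intervals for shares and conditional binomial intervals for ratios, at the 95% level. Log2 ratios had 0.5 added to each sum. A class was compared where both libraries held at least 50 of its cells, so T cells of IgG (15) and melanoma-like cells of PD1/LAG3 (4) were left out. There were 10 comparisons: each treatment with IgG, each combination with its single agents, and the 2 combinations with each other. No test was made, because each group has 1 library and cells are not replicates. A gene entered a list median with at least 20 UMIs over the 2 libraries, and a median needed 5 members. Its interval comes from 1000 Poisson draws, and its percentile from 10000 random lists matched in level over 20 bins. The 22 lists, written before the counts were seen, cover antigen presentation by MHC class I and class II, interferon-gamma and type I interferon responses, S phase, mitosis, chemokines, checkpoint ligands, hypoxia and glycolysis, extracellular matrix, oxidative phosphorylation, dissociation stress, apoptosis and p53, dedifferentiated melanoma, 3 macrophage states (inflammatory, alternatively activated, lipid-associated) and 5 T cell states (cytotoxic effector, inhibitory receptor and exhaustion, regulatory, type 1 helper, naive and memory). Shares of cells with a UMI of a gene were taken after drawing each cell down to 1000 UMIs, with shallower cells left out.

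Genes were named by a fixed rule for each combination against IgG and for the 2 combinations against each other. The rule takes the 5 higher and 5 lower genes whose interval bound nearest 0 lies farthest from 0. It covers genes with at least 100 CPM in a library of the pair and a mean of at least 0.25 of the highest class. Class markers, mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes and unnamed gene models were left out. Up to 4 measured members of a list with the highest mean are also named, and Pdcd1, Lag3 and Ctla4 in every library. A ratio against a count of 0 is given as a lower bound against 3 counts.

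The median of all genes was itself off 0 in some pairs. In macrophages or monocytes against IgG it was -0.36 for PD1/LAG3 (7973 genes), -0.22 for anti-CTLA4, -0.17 for anti-PD1 and -0.11 for PD1/CTLA4. For PD1/LAG3 it was -0.16 against PD1/CTLA4, -0.25 against anti-LAG3 and -0.19 against anti-PD1. In melanoma-like cells it was -0.19 for anti-PD1, -0.13 for PD1/CTLA4 and -0.11 for anti-CTLA4, each against IgG. Ratios below are to be read against these shifts. The ratio and interval steps were tested on counts simulated from the real class sums with counting error only. Filtering, clustering, naming and list medians were not tested. Spread between tumours was not simulated, so the rates say nothing of differences between single tumours. Of genes given a log2 change of 1, the interval excluded 0 for 68.0% in macrophages or monocytes (7990 genes tested), 89.0% in melanoma-like cells (12621) and 71.0% in T cells (7810). For a log2 change of 2 these were 99.0%, 98.0% and 96.9%, and for unchanged genes 4.12%, 4.47% and 4.10%. Alternatives covered the clustering, naming, cell filter, doublets, scaling, minimum count, added count, thinning depth and equal weight per cell. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.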

Results

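Melanoma-like cells made up 77.6% of the IgG library (95% interval 75.2 to 79.7, 1064 of 1372 cells) and 0.206% of the PD1/LAG3 library (0.0561 to 0.526, 4 of 1945). They made up 60.3% of the PD1/CTLA4 library (56.8 to 63.7, 478 of 793), 52.4% with anti-LAG3, 31.0% with anti-PD1 and 19.0% with anti-CTLA4. T cell-like cells were 1.09% of IgG (0.613 to 1.80, 15 cells), 42.2% of PD1/LAG3 (40.0 to 44.4, 820 cells) and 16.6% of PD1/CTLA4 (14.1 to 19.4, 132 cells), with 24.6%, 12.6% and 30.1% under anti-PD1, anti-LAG3 and anti-CTLA4. Macrophages or monocytes were 19.5% of IgG, 39.4%, 30.4% and 38.8% of the 3 single-agent libraries in the same order, 8.64% of PD1/LAG3 (168 cells) and 19.7% of PD1/CTLA4 (156 cells). All intervals cover counting error only, and no difference between libraries has a replicate check.

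Among immune cells alone, T cells were 5.0% in IgG, 64.2% in PD1/LAG3 (61.5 to 66.8) and 42.4% in PD1/CTLA4 (36.9 to 48.1). Fibroblast-like cells (308) and endothelial cell-like cells (329) together were 32.8% of PD1/LAG3 (30.7 to 34.9) and at most 3.46% of any of the other 5 libraries. B cell-like cells were 6.48% of PD1/LAG3 and 0.252% of PD1/CTLA4, and neutrophil-like cells 4.01% and 0.504%. With 15 principal components no library had a B cell-like cluster, and with the stricter cell filter neutrophil-like cells were 1.98% of PD1/LAG3. NK cell-like cells ranged from 0.875% in IgG to 3.52% with anti-CTLA4 (0.510% and 2.22% with classes from own markers) and were 3.29% of PD1/LAG3 (1.34% with own markers, 0.977% with 15 components). Dendritic cell-like cells ranged from 0.292% in IgG to 1.17% with anti-CTLA4, and formed no class with 15 principal components or at Leiden resolution 0.5. The T cell share of PD1/LAG3 depends on the rule for naming clusters, because 63.8% of those T cells lie in cluster 6 (523 cells) and that cluster has no name when leading genes are ranked by fold over all other cells. That ranking, the first one chosen, gives 15.3% for PD1/LAG3 and 15.1% for PD1/CTLA4 over all cells, and 39.4% (35.9 to 43.0) and 41.5% (35.8 to 47.4) over immune cells, so the higher T cell share of PD1/LAG3 is not seen with it. Cluster 6 had 14 T cell markers present, with Cd3e, Cd3g, Cd8b1 and Icos among its leading genes in the main ranking. The first ranking therefore leaves cells with T cell markers out of the count. Over 8 alternative settings, that ranking included, the PD1/LAG3 share over all cells ran from 15.3% to 44.3%. The pigment genes Dct and Tyr, which melanocytes use to make melanin, had 0 UMIs in all kept cells of PD1/LAG3 (upper limit 0.601 CPM), against 352.7 and 234.5 CPM in IgG.

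**Figure D1:**
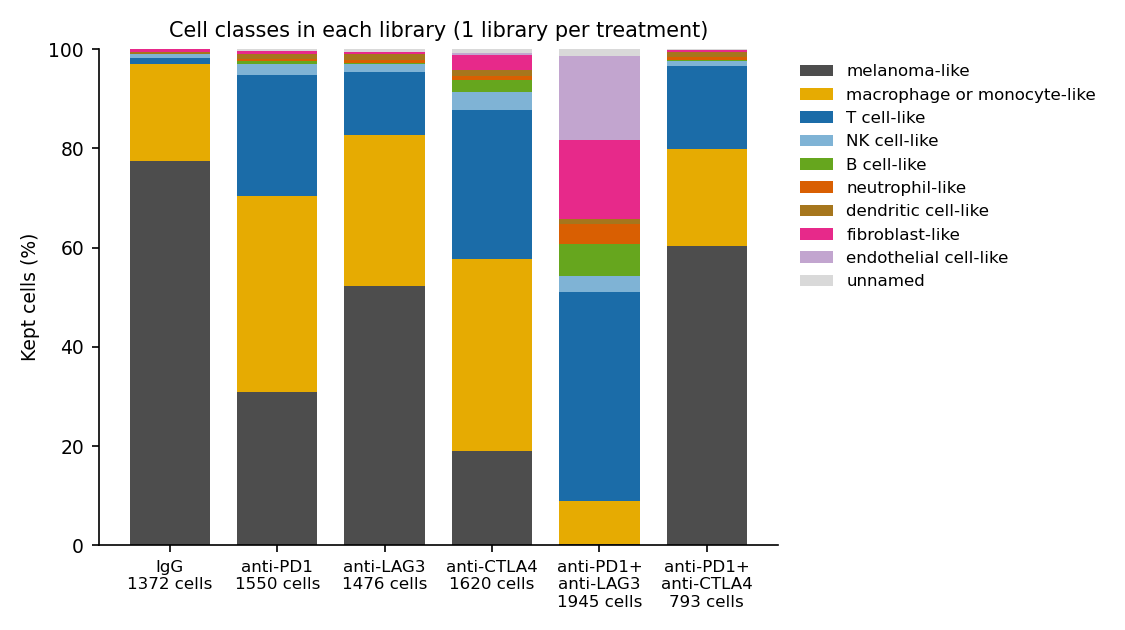
Share of kept cells in each cell class for the 6 libraries. Each library is a single sample, so the shares have no replicate spread.

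In melanoma-like cells of the PD1/CTLA4 combination, interferon-response and antigen-presentation genes were higher than in IgG, and cell-cycle genes were lower. The interferon-gamma list had a median log2 ratio of 3.48 (3.34 to 3.64, 18 of 18 genes higher) and the type I interferon list 4.38 (4.01 to 4.41, 16 of 16). MHC class II genes were higher by 3.08 (3.04 to 3.12, 8 of 8) and MHC class I genes by 1.63 (1.58 to 1.68, 13 of 13). S phase genes stood at -0.72 (-0.81 to -0.66, 14 of 14 lower) and mitosis genes at -0.87 (-0.93 to -0.82, 14 of 14 lower), for 478 cells against 1064. Each of these 6 medians lay beyond all 10000 random lists. Cluster 8, which has Ube2c among its leading genes, held 20.6% of the IgG melanoma-like cells and 8.37% of those of PD1/CTLA4 (10.8%, 5.82% and 12.0% with anti-PD1, anti-LAG3 and anti-CTLA4), and all 17 cells of cluster 22 came from PD1/CTLA4.

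The 5 genes named by the rule as higher in PD1/CTLA4 melanoma-like cells were Zbp1, Gbp4, Iigp1, Gbp6 and Isg15. Zbp1, a nucleic acid sensor (chromosome 2, 173206612 to 173218923 in GRCm38), reached 149.3 CPM against 7.10 in IgG, a log2 ratio of 4.39 (4.19 to 4.61). Gbp4 (chromosome 5, 105115767 to 105139586) stood at 206 against 10.7 CPM, Gbp6 at 141 against 7.88, Iigp1 at 524 against 31.2 and Isg15, a ubiquitin-like protein, at 224 against 14.8. Other members were higher by 2.92 (Irgm1), 3.17 (Ifi47), 3.97 (Rtp4) and 4.73 (Oasl2). Among presentation genes, the invariant chain gene Cd74 was at 1554 against 192 CPM and H2-Aa was 3.47 higher, while B2m, H2-K1 and H2-D1 were 0.79, 0.96 and 0.85 higher and the immunoproteasome gene Psmb8 1.81 higher. Cxcl10, which draws in T cells, was higher by 5.48 (5.06 to 5.95) and Ccl5 by 2.62, with a chemokine median of 2.79. Cd274, which encodes the PD1 ligand, was 2.30 higher (2.03 to 2.58), Lgals9 2.57 and Cd47 0.43. The checkpoint ligand median of 2.30 was 0.43 with at least 100 UMIs per gene, and with equal weight per cell the chemokine median was 4.25 and the type I interferon median 3.69. With leading genes of clusters ranked by fold over all other cells the chemokine median was 1.84.

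Some immune RNA in melanoma-like cells was also higher in PD1/CTLA4 than in IgG, compared without drawing down. Gzmb was seen in 2.51% against 0.0940% of cells. Cd8a was seen in 0.837% against 0.0940%, with overlapping intervals. Shares were lower for Foxp3 (0.209% against 1.03%), Tcf7 (8.16% against 8.74%) and Lag3, also with overlapping intervals. The Tcf7 shares are not read as T cell RNA, because IgG held 15 T cells, of which 1 had a Tcf7 UMI. Cd4, Pdcd1, Ctla4 and Ifng were each seen in 1 PD1/CTLA4 cell. Median depth was 15340 against 30564 UMIs. Limits on RNA carried over from another class, set by the level of its markers, were computed after the results were seen. In PD1/CTLA4 melanoma-like cells macrophages or monocytes can give at most 1.54% of the MHC class II UMIs, 2.10% of Cd74, 0.486% of the interferon-gamma list, 1.06% of the type I interferon list and 1.59% of Cxcl10. For Ccl5 the limits are 7.28% from macrophages or monocytes and 8.78% from T cells, and for the chemokine list 19.4% and 7.16%. For Cxcl9 (6.28 CPM) the limit is 61.3%, and 102% in IgG, so its ratio of 4.42 is not read as a change of melanoma-like cells. Dendritic cell markers set no useful limit for MHC class II (114%), Cd74 (174%), Cxcl10 (212%), Ccl5 (718%) or the chemokine list (485%). Their limit was 16.2% for the interferon-gamma list and 63.3% for the type I interferon list. The dendritic cell marker Fscn1 is a leading gene of melanoma cluster 5, and no limit was computed without it.

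Lower in PD1/CTLA4 melanoma-like cells were the linker histone genes Hist1h1b (65.3 against 161 CPM) and Hist1h1e (69.5 against 162), Lmnb1 of the nuclear lamina (50.5 against 121), the endocytic adaptor gene Hip1 (65.0 against 141) and the hexokinase gene Hk1 (70.8 against 151). Ube2c, Top2a, Cdk1 and Tpx2, all used in mitosis, were at -0.87, -0.99, -0.81 and -0.95, and the replication genes Pcna, Mcm7, Mcm4 and Mcm3 at -0.55, -0.57, -0.73 and -0.79. Extracellular matrix genes had a median of -0.50, with Fn1 at -0.82 and Col4a1 at -0.56. Hypoxia genes were at -0.30, with Eno1 at -0.62 and Aldoa at 0.22. Small medians were seen for oxidative phosphorylation (-0.02), apoptosis and p53 (0.15), dedifferentiated melanoma (0.12) and dissociation stress (0.37, with Fos 0.41 higher).

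The 3 single agents had the same directions as PD1/CTLA4 for interferon, MHC and cell-cycle genes in melanoma-like cells against IgG, which is the same single library in all 4 comparisons, in 480, 773 and 308 cells. Interferon-gamma medians were 3.58 with anti-PD1, 2.56 with anti-LAG3 and 3.66 with anti-CTLA4, and MHC class II medians were 3.69, 2.37 and 3.51. Type I interferon medians were 4.12, 3.05 and 3.30 (2.55 for anti-CTLA4 with equal weight per cell) and MHC class I medians 1.69, 1.27 and 1.59. Iigp1 was higher by 4.09, 3.19 and 3.77, Cd74 by 3.84, 2.83 and 3.75, and Cxcl10 by 4.97, 4.48 and 5.75. S phase genes stood at -0.85, -0.65 and -0.81. Mitosis genes were at -0.73, -1.39 and -0.77, with Ube2c at -1.72 under anti-LAG3. Extracellular matrix genes were 0.51 higher with anti-CTLA4 (Fn1 1.04, Col4a1 0.59) and lower with anti-LAG3 (-0.29). With anti-PD1 they stood at -0.20, where the median of all genes was -0.19. Dissociation stress genes were higher in all 3, by 0.31, 0.86 and 0.20.

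**Figure D2:**
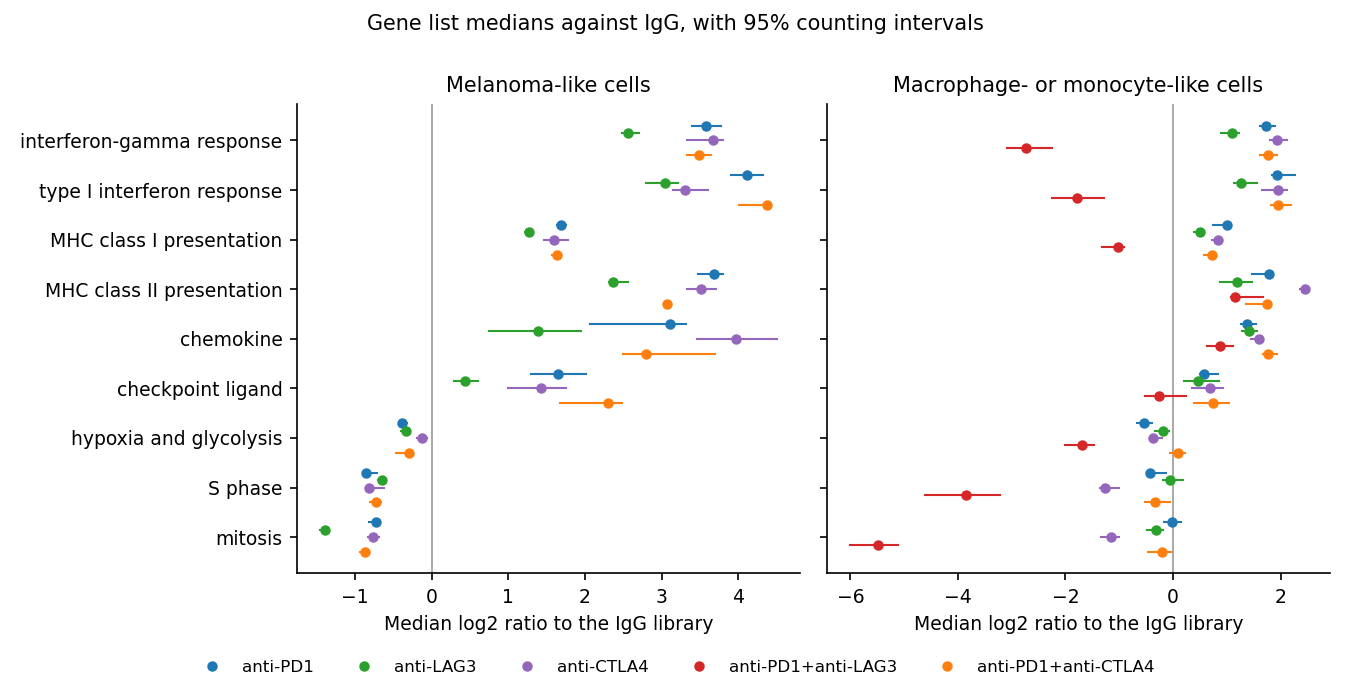
Median log2 ratio of each gene list against IgG in melanoma-like cells and in macrophages or monocytes. Lines show the 95% counting interval of the median, and each treatment is a single library.

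Against its single agents, the PD1/CTLA4 combination differed little in the interferon-gamma genes of melanoma-like cells. The median was 0.01 against anti-PD1 (-0.05 to 0.05, 9 of 18 genes higher) and 0.08 against anti-CTLA4 (-0.02 to 0.16). MHC class II genes were lower in the combination, by -0.50 against anti-PD1 (Cd74 -0.83, H2-Aa -0.69) and -0.47 against anti-CTLA4 (Cd74 -0.73). Type I interferon genes stood at -0.01 against anti-PD1 and were 0.68 higher than with anti-CTLA4 (0.50 to 0.84, 14 of 16 genes), with Rtp4 0.99 and Oasl2 0.60 higher. Extracellular matrix genes were lower than with anti-CTLA4 (interval of the median -1.18 to -0.86, 8 of 8 lower). Fn1 was at -1.86, Col4a1 at -1.15 and Col4a2 at -1.08. Cd274 was 0.87 higher than with anti-CTLA4 (0.54 to 1.22), while Ccl5 was at -1.34. The chemokine medians of 0.89 against anti-PD1 and -0.73 against anti-CTLA4 turned direction under other settings, to -0.28 with doublets kept and to 1.36 with equal weight per cell, and the latter was between -1.46 and -1.67 under 5 other settings and lower still with leading genes ranked by fold over all other cells.

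In macrophages or monocytes of the PD1/LAG3 combination, genes of the lipid-associated list were higher than in IgG, and interferon-response, cell-cycle and glycolysis genes were lower. The lipid-associated list had a median of 2.27 (2.24 to 2.31, 11 of 11 genes higher) and the alternatively activated list 1.68 (9 of 9 higher). The interferon-gamma list was at -2.73 (-3.10 to -2.25, 16 of 17 lower; -2.63 with its gene at 0 counts set to 3 counts), type I interferon genes at -1.79 (10 of 12 lower) and MHC class I genes at -1.02 (12 of 13 lower). MHC class II genes were 1.15 higher (6 of 8). S phase genes stood at -3.85 (-3.72 with 3 counts for a 0, -3.11 with 2 added, -3.19 at Leiden resolution 0.5) and mitosis genes at -5.49 (-3.87), 14 of 14 lower, for 168 cells against 268. Of the PD1/LAG3 cells 75.0% lie in cluster 4 and 25.0% in cluster 7. Of the IgG cells 56.0% lie in cluster 2 and 33.2% in cluster 13.

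Retnla, an alternative-activation gene (chromosome 16, 48842551 to 48844461), had 985 UMIs in PD1/LAG3 macrophages or monocytes and 0 in IgG, at least 730-fold higher. Lyz1, a lysozyme gene, had 315 and 0 UMIs, at least 233-fold higher. Thbs1 was higher by 9.59 (8.26 to 12.09, 1214 against 3 UMIs), the scavenger receptor gene Cd36 by 8.06 (6.86 to 10.11; 7.14 with 15 components, 8.88 with equal weight per cell) and Cd5l by 7.45 (6.55 to 8.75, 894 against 4.82 CPM; 11.54 with the stricter cell filter, 6.77 with equal weight per cell). Apoe, a lipid carrier gene, was 2.27 higher, Lgals3 1.93, Ctsb 1.54 and Ctsd 1.35. Cxcl2 was 3.28 higher, Ccl6 2.38, Arg1 1.68 and Tnf 1.56. Cxcl2 is also a leading gene of the neutrophil cluster and Cd36 of the endothelial cluster, and carried-over RNA of those cells can give at most 3.99% and 3.63% of their UMIs here. The inflammatory median was 0.48 (1.56 with at least 100 UMIs per gene) and the chemokine median 0.86. The p53 target genes Gdf15, Mdm2 and Cdkn1a were higher by 4.18, 2.18 and 1.19, in an apoptosis and p53 list with 6 of 10 genes higher and a median of 0.76 (1.35 with at least 100 UMIs per gene).

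Lipg, a lipase gene, had 0 UMIs in PD1/LAG3 and 589 in IgG macrophages or monocytes, at least 88.3-fold lower, and Fcrl5 (0 against 409) and Klra17 (0 against 312) were at least 61.3-fold and 46.8-fold lower. Cd300e was at -6.27 (-9.64 to -4.73, 2 against 429 UMIs; -4.84 with equal weight per cell, -7.00 with own markers) and Hist1h1b at -6.52 (-12.41 to -4.62, 1 against 306; -7.59 with equal weight per cell, -5.53 with 2 added). Cxcl9 stood at 13.4 against 434 CPM, a log2 ratio of -4.95 (-6.08 to -4.13), with Gbp2 at -2.93, Cd274 at -2.03, Psmb8 at -2.06 and Irf7 at -1.70. The glycolysis genes Aldoa, Pgk1 and Ldha were at -2.49, -2.08 and -1.56, with a hypoxia list median of -1.69 (12 of 14 lower). Oxidative phosphorylation was at -0.44 and checkpoint ligands at -0.27. Dissociation stress was 0.36 higher, with Junb at 0.82 and Fos at -1.38.

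In macrophages or monocytes of the PD1/CTLA4 combination, interferon, inflammatory and antigen-presentation genes were higher than in IgG. The interferon-gamma median was 1.77 (1.62 to 1.94, 18 of 18 higher), type I interferon 1.95 (14 of 14), inflammatory 2.19 (9 of 9), MHC class II 1.74 (8 of 8) and MHC class I 0.72 (12 of 13), for 156 cells against 268. Ly6i was higher by 7.41 (6.07 to 9.92, 279 against 3 UMIs) and Nos2, which makes nitric oxide (chromosome 11, 78920787 to 78960254), by 6.34 (5.12 to 8.40, 219 against 2.41 CPM). The protease inhibitor gene Slpi was higher by 5.18 (4.21 with equal weight per cell), Upp1 by 4.38 and the arginine-cycle gene Ass1 by 4.21. Cxcl9 was at 1483 against 434 CPM (1.77 higher), Cxcl10 was 3.03 higher, Ccl5 4.34, Ccl8 2.09, Il1b 1.82, Arg1 2.85 and Isg15 2.67. Lag3 (23.2 against 0.603 CPM) and Ctla4 (19.3 against 0), read mainly in T cells, were also higher here, while the intervals of Pdcd1 overlapped. Ccl5 was at 3482 CPM in T cells of PD1/CTLA4, and no limit on T cell RNA carried into macrophages or monocytes was computed. Lipg stood at -3.98 (-4.81 to -3.33), Cxcl14 at -3.60 (-4.49 with equal weight per cell), Sort1 at -3.47, Ddit4 at -2.42 and Clec4b1 at -2.14. Apoe was at -1.22 while Lgals3 was 1.02 higher, inside a lipid-associated median of 1.02. S phase (-0.33) and mitosis (-0.21) genes lay near IgG, and dissociation stress was at -0.23. Of these cells 39.7% lie in cluster 4 and 21.8% in cluster 7, which has Cxcl9, Ly6i and Cfb among its leading genes, while IgG has 9.70% and 1.12% there. Within cluster 2, looked at after the results were seen, the interferon-gamma median against IgG was 1.74 (1.48 to 2.05, 50 against 150 cells).

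Under the single agents the interferon-gamma median of macrophages or monocytes against IgG was 1.73 with anti-PD1, 1.10 with anti-LAG3 and 1.92 with anti-CTLA4. Cluster 7 held 18.4%, 9.60% and 26.4% of these cells and 1.12% of those of IgG, and cluster 13 held 11.8%, 20.5% and 1.91% against 33.2% in IgG. Cluster 7 also held 25.0% of PD1/LAG3 cells, whose interferon-gamma median was below IgG, so its share does not track these genes in every library. Within cluster 2 the medians of the single agents were 1.85, 0.91 and 1.96. Inflammatory medians were 1.97, 1.37 and 1.88 and alternatively activated medians 1.89, 1.71 and 1.30. MHC class II medians were 1.78, 1.19 and 2.46. With anti-PD1, Cxcl9 was 1.99 higher, Cxcl10 3.17 and Isg15 2.71, and Apoe stood at -0.86. S phase and mitosis genes were at -1.27 and -1.15 with anti-CTLA4, against -0.43 and -0.01 with anti-PD1 and -0.06 and -0.32 with anti-LAG3.

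Set against each other, macrophages or monocytes of PD1/LAG3 had lower interferon, MHC class I, cell-cycle and glycolysis genes than those of PD1/CTLA4, and higher lipid-associated genes. The interferon-gamma median was -4.15 (-4.79 to -3.84, 18 of 18 lower), type I interferon -4.01 (14 of 14), MHC class I -1.40 (13 of 13), inflammatory -2.05 and hypoxia -1.84, for 168 against 156 cells. The lipid-associated median was 1.47 (1.19 to 1.79, 11 of 11 higher), while MHC class II stood at -0.10 and alternatively activated genes at 0.18. Cxcl9 (chromosome 5, 92321347 to 92328079) was at 13.4 against 1483 CPM, a log2 ratio of -6.72 (-7.85 to -5.91). With equal weight per cell it was -5.19. Cfb was at -6.34 (-8.39 to -5.14), or -4.88 with equal weight per cell, Ly6i at -6.75 (-10.12 to -5.20), or -5.47 with equal weight per cell and -7.42 with own markers, and Ly6a at -5.52 (-6.23 to -4.94). Nos2 had 0 against 170 UMIs, at least 54.4-fold lower. Gbp2 was at -4.29, Cxcl10 at -5.17, Isg15 at -3.85, Irf7 at -3.47 and Psmb8 at -2.91.

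Higher in PD1/LAG3 than in PD1/CTLA4 macrophages or monocytes were Cd5l by 7.27 (6.08 to 9.32; 6.50 with equal weight per cell), the cell-cycle inhibitor gene Cdkn1c by 7.18 (5.27 to 13.07, 208 against 1 UMIs; 5.98 with equal weight per cell), Lyz1 by 5.66 (4.91 with equal weight per cell), Cd36 by 4.36, Thbs1 by 4.17, Retnla by 4.08, Apoe by 3.49 and Cxcl2 by 2.96. Gdf15 was 3.32 higher and Ctsd 1.93. Mitosis genes had a median of -4.46 (-3.78 with 3 counts for a 0) and S phase genes of -3.56. Dissociation stress was 0.97 higher, with Jund 1.35 and Junb 1.03, and apoptosis and p53 stood at 0.00. Most of the PD1/LAG3 cells lie in cluster 4 (75.0%), where 39.7% of the PD1/CTLA4 cells lie. Cluster 7 held 25.0% of the PD1/LAG3 cells and 21.8% of the PD1/CTLA4 cells.

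T cells of PD1/LAG3 had fewer cell-cycle transcripts than those of PD1/CTLA4, less Gzmb and more of the genes of naive and memory T cells. Mitosis genes had a median of -6.97 (-7.51 to -6.32, 13 of 13 lower; -5.41 with 3 counts for a 0) and S phase genes of -3.27 (-3.62 to -2.82, 11 of 12 lower; -2.29 with at least 100 UMIs), for 820 against 132 cells. Within cells with Cd8a or Cd8b1 and no Cd4 (470 against 110), S phase genes were at -3.19. Drawing every T cell down to 1000 UMIs left 7 S phase genes measured, at -1.41 (-2.22 to -0.80, 6 of 7 lower), and the same 7 were at -1.85 (-2.37 to -1.61) undrawn, so the size of this difference depends on which genes are measured. The cytotoxic effector median was -0.67 (-0.84 to -0.57, 10 of 14 lower, percentile 1.59). The naive and memory median was 1.94 (1.63 to 2.26, 7 of 8 higher; 1.24 with equal weight per cell). Where leading genes are ranked by fold over all other cells, which leaves cluster 6 out of the PD1/LAG3 T cells, the cytotoxic median is -2.01 and the naive and memory median 2.87. Median depth was 1789 against 3950 UMIs, and 63.8% of the PD1/LAG3 T cells lie in cluster 6 and 34.5% in cluster 9, while 55.3% of those of PD1/CTLA4 lie in cluster 3.

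Pclaf, Ube2c and Birc5, used in replication and division, had 1 UMI each in PD1/LAG3 T cells against 295, 181 and 171 in PD1/CTLA4, log2 ratios of -8.87 (-14.76 to -6.96), -8.16 and -8.08, or -7.87, -7.17 and -7.09 with 2 added. Cenpf was at -7.28, and Ccna2 (0 against 77 UMIs) was at least 60.8-fold lower. Mki67 was at -5.03 (-5.97 to -4.29) and Top2a at -3.53, while Pcna was at 0.08. Gzmb, a cytotoxic granule protease (chromosome 14, 56258838 to 56262260), stood at 403 against 2308 CPM, a ratio of -2.52 (-2.65 to -2.38). Ccl3, Ccl4 and Nkg7 were at -4.00, -2.03 and -0.61, whereas Ccl5 was 1.82 higher (1.76 to 1.88). Il7r, Klf2 and Ccr7, which mark recirculating and memory cells, were higher by 1.91, 1.72 and 2.16, and Ltb was at -0.21. The glycolysis genes Pgk1, Aldoa and Ldha were at -3.07, -2.97 and -2.28.

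Nr4a3, an activation-induced nuclear receptor gene (chromosome 4, 48045153 to 48086447), was at 1262 CPM in PD1/LAG3 T cells and 55.1 in PD1/CTLA4, a ratio of 4.50 (4.06 to 5.02). Fosl2 was higher by 4.44 (3.91 to 5.09), Kdm6b by 4.46, Mpp7 by 4.40 (5.30 with equal weight per cell), Ramp3 by 3.94 (4.97 with leading genes ranked by fold over all other cells) and Nr4a2 by 2.48. The dissociation stress list, which holds related early-response genes, was 1.23 higher (11 of 14), with Junb at 1.35 and Jund at 1.14. Regulatory T cell genes were 0.98 higher (8 of 10), with Icos 1.19 and Tnfrsf4 0.97. This median was 0.22 with equal weight per cell and 1.79 with leading genes ranked by fold over all other cells. Foxp3 was seen in 0.678% of drawn-down PD1/LAG3 T cells (0.220 to 1.57) and 1.59% of those of PD1/CTLA4 (0.193 to 5.62). Undrawn, the Foxp3 shares were 1.71% and 2.27%, also with overlapping intervals. A larger share of regulatory T cells in PD1/LAG3 is therefore not read from this list. It is not excluded either, as the drawn-down Foxp3 shares rest on only 5 and 2 cells. Subcluster 3 of T and NK cells had 6 regulatory T cell markers present, with Foxp3 and Cd4 among its leading genes. It stayed unnamed because more of its leading genes mark another subset. It held 175 PD1/LAG3 and 9 PD1/CTLA4 cells, of 884 and 140 T and NK cells. The inhibitory receptor and exhaustion median was -0.45 (7 of 12 lower, percentile 11.2), type 1 helper -0.12, interferon-gamma response -0.92 and apoptosis and p53 0.77. Ifng was at -0.74 and Stat4 1.53 higher.

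The antibody targets were compared in T cells of every library. Pdcd1 (chromosome 1, 94038305 to 94052553) was at 437 CPM in PD1/LAG3 (405 to 470) and 727 in PD1/CTLA4 (665 to 794), against 500, 679 and 532 with anti-PD1, anti-LAG3 and anti-CTLA4. Lag3 (chromosome 6, 124904361 to 124911705) was at 115 in PD1/LAG3 (99.2 to 133), 317 in PD1/CTLA4 (277 to 362) and 544, 599 and 683 with the single agents. Ctla4 (chromosome 1, 60887000 to 60915832) was at 498 in PD1/LAG3 (464 to 534), 401 in PD1/CTLA4 (355 to 451) and 624, 633 and 411 with the single agents. The 15 T cells of IgG gave 788, 370 and 513 for the 3 genes.

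With each T cell drawn down to 1000 UMIs, Cd8a was seen in 34.4% of PD1/LAG3 T cells (31.0 to 38.0, 738 cells) and 57.1% of PD1/CTLA4 T cells (48.0 to 65.9, 126 cells), and Cd4 in 12.1% (9.80 to 14.6) and 3.97% (1.30 to 9.02). Without drawing down, the Cd8a shares were 46.5% and 82.6% and the Cd4 shares 18.8% and 8.33%. Drawing down left out 82 and 6 shallower cells, and the median depths of all T cells were 1789 and 3950 UMIs. Gzmb was seen in 21.4% (18.5 to 24.5) and 56.3% (47.2 to 65.2), or 28.3% and 72.7% undrawn, and Mki67 in 1.08% (0.469 to 2.12) and 12.7% (7.44 to 19.8), or 1.71% and 34.1%. Tcf7, a memory factor, was seen in 5.83% (4.25 to 7.77) and in 0 of 126 cells (0 to 2.89), where 3 cells would be 2.38%. Undrawn, the Tcf7 shares were 9.15% (7.26 to 11.3) and 5.30% (2.16 to 10.6, 7 of 132), with overlapping intervals. Where leading genes are ranked by fold over all other cells, cluster 6, which has Cd8b1 among its leading genes, is left out of the T cells. The PD1/LAG3 T cells that remain have Cd8a in 5.62%, Cd4 in 33.3% and Gzmb in 2.41%. Melanoma-like cells of PD1/CTLA4 (466 cells, 12 left out, median depth 15340) served as a free RNA background. They had Cd8a in 0.644%, Gzmb in 0.858% and Cd4 in 0. Their Mki67 share of 3.86% includes their own division. Their Tcf7 share of 1.07% is not read as free T cell RNA. Undrawn melanoma-like cells of IgG had Tcf7 in 8.74%, although that library held only 15 T cells. PD1/LAG3 holds too few melanoma-like cells for such a background, and its fibroblast- and endothelial cell-like cells (589 cells, 48 left out, median depth 3459) had Cd8a in 0.849%, Cd4 in 0.340%, Gzmb in 0.170%, Mki67 in 0.509% and Tcf7 in 0.340%.

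**Figure D3:**
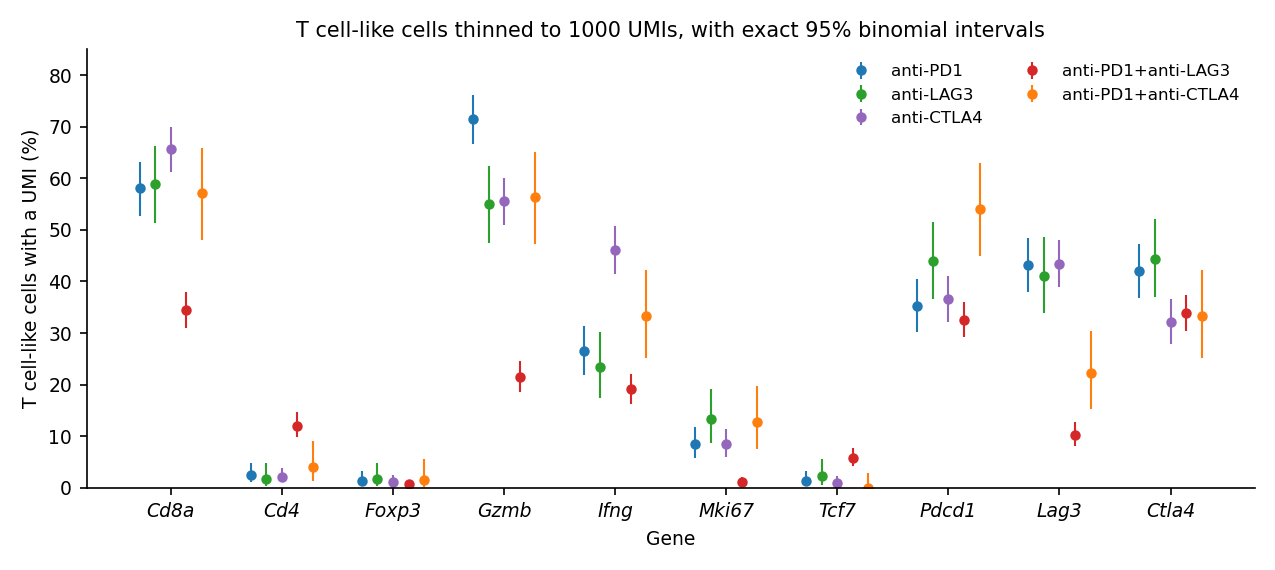
Percent of T cell-like cells with at least 1 UMI of each gene after each cell was drawn down to 1000 UMIs, with 95% binomial intervals. Each treatment is a single library.

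Cells in cycling subclusters were 1.58% of T and NK cells in PD1/LAG3 (0.868 to 2.64, 14 of 884) and 33.6% in PD1/CTLA4 (25.8 to 42.0, 47 of 140). They were 22.8% with anti-PD1, 37.7% with anti-LAG3 and 20.2% with anti-CTLA4. Subcluster 2, with Pclaf, Mcm3 and Birc5 among its leading genes and 4 cycling markers present, stayed unnamed because it had under 2 leading cycling markers. It held 125 cells of anti-PD1, 57 of anti-LAG3, 61 of anti-CTLA4, 21 of PD1/CTLA4 and 0 of PD1/LAG3. The size and order of the cycling shares outside PD1/LAG3 therefore depend on this naming rule. The anti-LAG3 share was between 23.8% and 24.5% under 5 other settings, and with leading genes ranked by fold over all other cells it was 18.2% and that of anti-CTLA4 11.7%. The PD1/LAG3 share ran from 0 to 5.68% over other settings. NK subclusters were 5.20% and 3.57% of these cells in the 2 combinations, or 11.4% and 5.71% at Leiden resolution 0.5, and 10.8% in PD1/LAG3 with that other ranking.

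Against anti-PD1 and anti-LAG3 alone, T cells of PD1/LAG3 had lower cytotoxic and mitosis genes and higher naive and memory genes. The cytotoxic effector median was -1.55 against anti-PD1 (-1.62 to -1.33, 13 of 16 lower) and -1.25 against anti-LAG3 (-1.51 to -1.19, 12 of 16). With leading genes ranked by fold over all other cells these were -3.35 and -3.03. Naive and memory genes were higher by 1.68 and 1.90 (2.89 and 2.94 with that ranking), 8 of 8 in each, with Il7r 3.01 and 2.23 higher. Mitosis genes stood at -6.73 and -7.17, or -4.65 and -5.07 with 3 counts for a 0. Gzmb was at -3.06 and -2.15 and Ccl3 at -4.35 and -3.92, while Ccl5 was higher by 0.70 and 0.85 and Nr4a2 by 2.26 and 2.07. Drawn-down T cells of PD1/LAG3 had Cd8a in 34.4%, against 58.0% with anti-PD1 and 58.9% with anti-LAG3. Cd4 was seen in 12.1%, against 2.54% and 1.67%. These T cell contrasts with the single agents were not repeated within CD8 cells, so another mix of CD4 and CD8 cells stays open for them. In macrophages or monocytes, PD1/LAG3 was at -4.29 and -3.56 for interferon-gamma genes, at -1.55 and -1.27 for MHC class I genes, and higher by 1.61 and 1.42 for lipid-associated genes. Dissociation stress was higher by 1.05 and 0.86 in these cells and by 1.16 and 0.87 in T cells.

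Against anti-PD1 and anti-CTLA4 alone, T cells of PD1/CTLA4 had lower cytotoxic effector genes, by medians of -0.38 (-0.51 to -0.25, 12 of 16 lower) and -0.98 (-1.23 to -0.90, 13 of 15), with 132 cells against 381 and 487. Ccl5 was at -1.12 and -1.46, and against anti-CTLA4 Ccl4 was at -0.91, Ccl3 at -1.33, Lag3 at -1.10 and Ifng at -0.98. Pdcd1 was higher by 0.54 and 0.45 and Mki67 by 0.62 and 0.49. Exhaustion genes stood at -0.38 and -0.43. Type 1 helper genes were 0.50 higher than with anti-PD1 (8 of 10) and lay at 0.04 against anti-CTLA4. MHC class II genes were at -1.26 against anti-CTLA4, or -0.60 with equal weight per cell, and dissociation stress at -0.45. In macrophages or monocytes, hypoxia genes were 0.42 higher than with anti-PD1 (16 of 16). Against anti-CTLA4, S phase and mitosis genes were higher by 0.94 and 0.91, with Top2a 1.29 and Mki67 1.28, while MHC class II genes were at -0.68 (8 of 8 lower) and Apoe at -1.45. Interferon-gamma genes lay at -0.04 and -0.17.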

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

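All tests in this part were chosen after the results were seen. In macrophages or monocytes against IgG, 3 gene lists had opposite directions in the 2 combinations with both medians outside the central 95% of random lists, and the difference was not tested. MHC class I genes were at -1.02 with PD1/LAG3 and 0.72 with PD1/CTLA4, interferon-gamma genes at -2.73 and 1.77, and type I interferon genes at -1.79 and 1.95. Dissociation stress (0.36 and -0.23), checkpoint ligands (-0.27 and 0.74), hypoxia (-1.69 and 0.09) and oxidative phosphorylation (-0.44 and 0.10) also had opposite signs, but at least 1 of the 2 medians lay inside that range.

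PD1/LAG3 held 4 melanoma-like cells among 1945, and those 4 had 0 UMIs of Dct, Mlana, Pmel and Sox10. Loss to the cell filter was tested with no filter, where melanoma-like cells were still 0.0995% of barcodes (upper limit 0.359%) against at least 18.0% in the other libraries. Bursting of melanoma cells in the loaded suspension would leave their RNA around other cells, but melanoma markers were at 9.18 CPM in PD1/LAG3 T cells (5.14 to 15.1) against 28.4 to 76.0 elsewhere. The same markers in macrophages or monocytes were highest in PD1/LAG3, at 271 CPM (235 to 311) against 142 to 229, but S100a1 and Mitf gave 191 of those 202 UMIs. The other 16 markers were at 14.7 CPM there (7.36 to 26.4) against 21.2 to 69.5, with an interval that overlaps those of anti-PD1 and anti-CTLA4, so this class alone does not decide it. Fibroblast-like and endothelial cell-like cells were 32.8% of this library, so a tumour cleared under the combination and a piece of other tissue with little tumour in it cannot be told apart with 1 library per treatment.

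Low interferon-gamma genes in PD1/LAG3 macrophages or monocytes against PD1/CTLA4 (-4.15) were set against 3 technical explanations. With each cell drawn down to 1000 UMIs the median was -3.95 (-5.34 to -3.47, 13 of 13 measured genes lower), which argues against depth for these genes. It rests on fewer genes than the undrawn median, and no undrawn value was computed for the same genes. Within cluster 4 it was -3.61 (-4.39 to -3.01, 126 against 62 cells, 13 of 13 measured genes lower), which argues against another mix of clusters as the only source. Cells of both libraries in cluster 4 may still be of different macrophage states, which was not tested. Free melanoma RNA can give at most 3.88% of the list in PD1/CTLA4. Treatment, the tissue sampled and the handling of each library all stay open, because each treatment has 1 library. PD1/LAG3 cells had the lowest median depth (2146 UMIs) and the highest median mitochondrial share (3.55%) of the libraries. Tissue dissociation was not among the explanations tested, and no biological explanation was tested.

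Few mitosis UMIs in PD1/LAG3 T cells (70 against 1313 in PD1/CTLA4, a log2 ratio of the sums of -5.47) were tested in the same way. Drawing cells down to 1000 UMIs gave -5.02, and cells with Cd8a or Cd8b1 and no Cd4 gave -5.39 (470 against 110 cells), which argues against depth and against another mix of CD4 and CD8 cells. Free melanoma RNA can give at most 0.817% of the mitosis UMIs in PD1/CTLA4. For S phase, 7 genes stayed measured after drawing all T cells down, at -1.41 (-2.22 to -0.80, 738 against 126 cells) and at -1.85 (-2.37 to -1.61) undrawn. Treatment, the tissue sampled and the handling of each library stay open here too.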

How the results depend on the processing

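Comparisons, gene lists, the rule for named genes and 16 alternatives were chosen before the data were examined. Leading genes of clusters were first ranked by fold over all other cells. This was replaced after the data were seen, because it left cluster 6 without a name, and the first ranking was kept as an alternative, which gives a PD1/LAG3 T cell share of 15.3% in place of 42.2%. The clustering without the PD1/LAG3 library and the setting of a 0 to 3 counts were added after seeing the data. Counted list medians kept their direction in 3182 of 3186 values over 16 settings, and 359 values moved beyond their counting interval. Named genes kept theirs in 718 of 718 values over 15 settings (9 moved). The list count covers 205 medians and leaves out most that lay inside the central range of random lists. A sign change counted as a reversal only where the main interval excluded 0. The 50 gene ratios were chosen because their intervals lay far from 0, so their kept direction says little. Of 424 class shares 38 moved, of 710 UMI shares 155 and of 106 subset shares 19. Medians that reversed were in melanoma-like cells of PD1/CTLA4: mitosis against anti-PD1 (0.0203 with equal weight per cell), and chemokines against anti-PD1 (-0.28 with doublets kept) and against anti-CTLA4 (1.36 with equal weight per cell, 0.16 with at least 5 UMIs). The melanoma-like share of PD1/LAG3 was 0.0514% with classes from own markers, and that of PD1/CTLA4 was 55.3% with no filter, 56.7% with doublets kept or own markers and 54.2% with leading genes ranked over all other cells. That ranking, which leaves cluster 6 out of the PD1/LAG3 T cells, gave a T cell cytotoxic median between the combinations of -2.01. The cytotoxic median was -0.93 with own markers and -0.55 with TMM or with size factors. The macrophage interferon-gamma median of PD1/LAG3 was -2.24 against IgG with equal weight per cell, and against PD1/CTLA4 -3.69 with equal weight and -3.78 with 2 added. The T cell mitosis median was -5.45 with 2 added and -5.41 with a 0 set to 3 counts, as both draw ratios of small counts toward 0. For the other moves the cause was not tested. No paired analysis was possible because each treatment has 1 library, and replicate numbers are only names. Leaving out a replicate does not apply. Depth limits the PD1/LAG3 library most, at a median of 2146 UMIs per cell.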

Other observations

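T cell receptor beta variable segments were not part of the comparisons and were looked at after the other results were seen. Of T cells with a Trbv UMI, 36.1% carried Trbv29 with anti-CTLA4 (31.3 to 41.1, 140 of 388 cells) and 32.6% carried Trbv17 with anti-LAG3 (25.8 to 40.0, 58 of 178). The leading segments were Trbv3 in PD1/CTLA4 (24.8%, 30 of 121), Trbv4 with anti-PD1 (16.6% of 314) and Trbv19 in PD1/LAG3 (15.4%, 67 of 434). The effective number of segments was 5.28 with anti-CTLA4, 5.28 with anti-LAG3, 7.40 in PD1/CTLA4, 9.34 with anti-PD1 and 12.3 in PD1/LAG3. Whether a library holds 1 tumour or several is not given in the sources used here, so these shares and numbers are not compared between libraries. In T cell subcluster 6, which has 137 of its 160 cells from anti-CTLA4 and is led by the granzyme genes Gzmd, Gzmf and Gzmc, 53.2% of cells with a segment carried Trbv29 (66 of 124). Receptor segments were not left out of the clustering, and the segment Trav6-7-dv9 is a leading gene of this subcluster. Segment use may therefore have helped to form it, so no link between Trbv29 and the granzyme genes is read from this share.

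Mlana, a melanocyte gene, had 242 UMIs in PD1/LAG3, all of them in fibroblast-like cells and spread over 108 cells, although Dct and Tyr were at 0 there. Cdkn2a had 80 UMIs in that library, 69 of them in fibroblast-like cells, and stood between 670 and 1007 CPM in the other 5. Within cells with Cd8a or Cd8b1 and no Cd4, the T cell contrast between the combinations was -0.68 for cytotoxic effector genes and 1.71 for naive and memory genes (470 against 110 cells).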
